A study of Escherichia coli with 6 samples.

How the data were processed

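RNA was extracted from Escherichia coli ATCC25922 grown in LB at 37 °C, in 3 untreated libraries and 3 libraries with schisandrin A. Libraries were prepared with a SMARTER mRNA-Seq kit and RNA integrity was assessed on a Bioanalyzer, per the labels' protocols. The aligner, the counting tool, their settings, the strandedness of counting, the rRNA removal and the trimming are not given in the sources used here. Overlapping genes and antisense pairs are therefore treated as uncertain.

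The authors deposited raw read counts per gene, with no normalization, for 4534 genes and 6 libraries. They also deposited FPKM values per library and a table that repeats these FPKM values and adds the mean FPKM of each group. All 27204 FPKM values of the second table equalled those of the first. The deposited FPKM equalled the FPKM computed from the deposited counts, coding length and library total, times a constant for each library, between 0.799 and 1.16, so the authors' FPKM carries a library scaling whose method is not given in the sources used here. Counts were the main input and FPKM was used only as an alternative. Column names matched the descriptions of single samples, and 0 columns of other samples were present.

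Gene identifiers are locus tags of E. coli K-12 MG1655, with symbols for RNA genes, although the strain sequenced is ATCC25922. Symbols came from a RefSeq gene table of MG1655 (assembly ASM584v2): 4351 identifiers matched a locus tag, 179 matched a symbol and 4 matched neither. Start and end equalled that table for 4331 of the 4351. Genes of ATCC25922 that MG1655 lacks were not analysed here, and 407 gene models had a count of 0 in all libraries. The files call every gene protein-coding; RNA classes were taken from the RefSeq table. The gene lengths are multiples of 3 for 96.4% of the models and hold no UTRs.

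Totals ranged from 1881510 to 2502328 counts per library, and a count of 3, the floor used here, corresponds to between 1.07 and 1.79 CPM. The floor covers counting error only. Bootstrap intervals resample genes and ranges of matched lists redraw genes, so neither covers the spread between libraries. Both draw genes independently, so neither covers correlation between genes. No library was left out of the main analysis.

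The comparison of schisandrin A with control used edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): filterByExpr, TMM factors, and the quasi-likelihood F test with a group term and no block, on 3830 genes passing the filter. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05; all adjusted p-values named edgeR come from this test. The common biological coefficient of variation was 0.103, and the prior degrees of freedom were infinite, so every gene's test used a spread pooled along the expression trend. Standard errors of log2 fold changes were computed as the absolute fold change over the square root of F. CPM values are scaled by TMM factors, which were 1.13 ± 0.101 in control and 0.889 ± 0.0149 in treated libraries (SD, n = 3).

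Before the data were examined, 52 gene lists were fixed from textbook knowledge of E. coli and matched by exact symbol; 51 had at least 5 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 51 lists, and with an estimated correlation and fry as alternatives. The genes named were chosen by a rule also fixed beforehand. It took the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 10 CPM in a group and no overlap between groups. It added up to 4 called members per described list in order of absolute fold change, and the most abundant member of each ribosomal protein list. Other genes named, such as the members that moved against their list and the virulence genes, were chosen after their values were seen.

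The tests were tried on simulated counts drawn for these genes, library sizes and this dispersion, with 200 genes changed. In that simulation edgeR ran on 3840 genes, and 6.38% of its calls were false. It recovered 68.7% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold. The simulation gave all genes the common dispersion and changed genes in random directions. It changed far fewer genes than the 1851 called in the data, so these rates may not carry over. Camera recovered a list shifted by -0.5 (log2) in 20 of 20 simulated data sets and called 0 of 999 unshifted list tests; genes were simulated as independent there.

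Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, other count filters, a minimum fold change of 1.5, a block for replicate number, leaving out stable RNAs or the 10 most abundant genes, and leaving out each library. A fold change from FPKM is on the log2(value + pseudocount) scale and understates changes of low genes.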

Results

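RNA was sequenced from Escherichia coli ATCC25922, a reference strain used in antimicrobial susceptibility testing, grown in LB medium at 37 °C with or without schisandrin A, a lignan of the Schisandra fruit. There were 3 control libraries and 3 libraries with schisandrin A; no dose, exposure time or cell density at harvest is given in the sources used here. Each library held between 1881510 and 2502328 reads counted in genes, with a mean of 2348808 ± 133055 for control and 2098243 ± 205728 for schisandrin A (SD, n = 3 each). The labels do not say that the replicates came from separate cultures, so the spread between these libraries may be technical. P-values and standard errors rest on that spread pooled over genes along the expression trend, not on each gene's own spread. The comparison asked which genes responded to the compound, and the study's title names ribosome function as its subject.

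Schisandrin A libraries differed from controls across a large part of the transcriptome. Genes for ribosomal proteins, translation, nucleotide synthesis, heat-shock chaperones and ATP synthase were mostly lower. In the lists of ribosome hibernation, acid resistance, RpoS general stress and anaerobic respiration, more genes were higher than lower. Of 3830 genes tested, 1851 (48.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 970 of them higher and 881 lower with schisandrin A. Among these, 231 were at least 2-fold higher and 185 at least 2-fold lower. Values of the control and treated groups did not overlap for 2074 genes, where chance alone gives 10% of genes for 3 libraries against 3. The split between higher and lower depended on scaling. With library size alone and no TMM factors, the median gene shifted by -0.34 (log2), and 531 genes were higher and 1650 lower. The genes changed at least 2-fold were then 108 higher and 480 lower. Changes below are relative to the TMM scale, and rises smaller than that shift vanish or reverse with library size alone.

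The first principal component of log2 CPM (counts scaled to library size) held 70.5% of the variance and separated the groups. Pearson's r across genes was 0.982 to 0.990 between libraries of a group and 0.938 to 0.946 between groups. No pair of libraries of a group agreed within sampling noise (chi-square of 2.57 to 6.47 per degree of freedom), so none was treated as a library deposited more than once.

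The largest rise was in preT (b2146), which encodes a subunit of dihydropyrimidine dehydrogenase, an enzyme of pyrimidine breakdown. It went from 32.6 ± 5.31 to 312 ± 9.77 CPM (SD, n = 3), a log2 fold change of 3.26 ± 0.14 (SE; adjusted p = 3.41e-118, edgeR). The narGHJI operon of the main respiratory nitrate reductase rose as a unit. Its first gene, narG, rose 6.75-fold from 235 ± 6.3 to 1587 ± 3.16 CPM, and narH, narJ and narI had log2 fold changes of 2.72 ± 0.12, 2.71 ± 0.12 and 2.69 ± 0.13. The trimethylamine N-oxide reductase gene torA and its chaperone gene torD rose by log2 values of 2.40 ± 0.12 and 2.42 ± 0.14. The neighbouring genes yjiX and btsT, the second encoding a pyruvate transporter, rose by 3.04 ± 0.29 and 2.52 ± 0.12. The acid-resistance membrane protein gene yhiM rose 6.73-fold, the phosphate-regulated ATPase gene phoH 6.61-fold, from 349 ± 31.8 to 2306 ± 63.3 CPM, and hchA, for a protein chaperone and glyoxalase, 5.91-fold.

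The largest fall was in ibpB (b3686), a small heat-shock protein gene, from 233 ± 24.4 to 21.9 ± 4.28 CPM, 10.7-fold lower (adjusted p = 4.69e-101, edgeR). Most of the other large falls were in nucleotide synthesis. The genes pyrB and pyrI, for the catalytic and regulatory chains of aspartate carbamoyltransferase, were 8.02-fold and 5.33-fold lower. The carbamoyl phosphate synthetase genes carA and carB were 4.85-fold and 5.71-fold lower. The purine pathway genes purM, purF and purT were 5.87-fold, 4.98-fold and 4.49-fold lower. The xanthine permease gene xanP was 6.3-fold lower. Glutamine synthetase, glnA, fell from 2184 ± 255 to 411 ± 16.3 CPM, and the membrane protein gene yoaE from 686 ± 74.2 to 92.7 ± 16.9 CPM. The gene yidD was 4.39-fold lower; it overlaps rnpA by 37 nt on the same strand, so their reads cannot be fully separated. Overlaps of yoaE with yoaL (13 nt) and of preT with preA (7 nt) are shorter.

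In the coordinates of the K-12 MG1655 gene models (assembly ASM584v2, chromosome), preT spans 2234033 to 2235271 on the plus strand. The narGHJI genes span 1279864 to 1286526 on the plus strand, with neighbouring open reading frames overlapping by at most 4 nt. The pyrI and pyrB genes lie on the minus strand from 4470986 to 4472395, carA and carB on the plus strand from 29651 to 34038, and ibpB on the minus strand from 3866469 to 3866897. These are positions of coding sequences.

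Ribosomal protein genes were lower as a group. Of the 54 tested, 47 fell, 6 did not pass the test and 1, rpmE for protein bL31, rose by 0.34 ± 0.12 (named after its value was seen), a rise that was 0.01 with library size alone. The median log2 fold change over both subunits was -0.73, a 1.66-fold fall, and single genes ranged from -1.59 to 0.34. In the large subunit, 26 of 33 genes fell and 1 rose. The steepest falls there were in the spc operon genes rplE (b3308), from 3353 ± 424 to 1113 ± 23 CPM, and rplN, from 1473 ± 140 to 496 ± 22.1 CPM. In the small subunit all 21 genes fell, led by rpsP (-1.29 ± 0.16) and rpsN (-1.28 ± 0.11), and rpsA, the most abundant, went from 5594 ± 925 to 3368 ± 79.7 CPM. Camera gave an adjusted p of 1.01e-09 for the large and 2.48e-10 for the small subunit list; with an estimated correlation each call was lost (adjusted p = 0.591 with an estimated correlation). Counts adjusted over the list alone were identical for both.

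**Figure D1:**
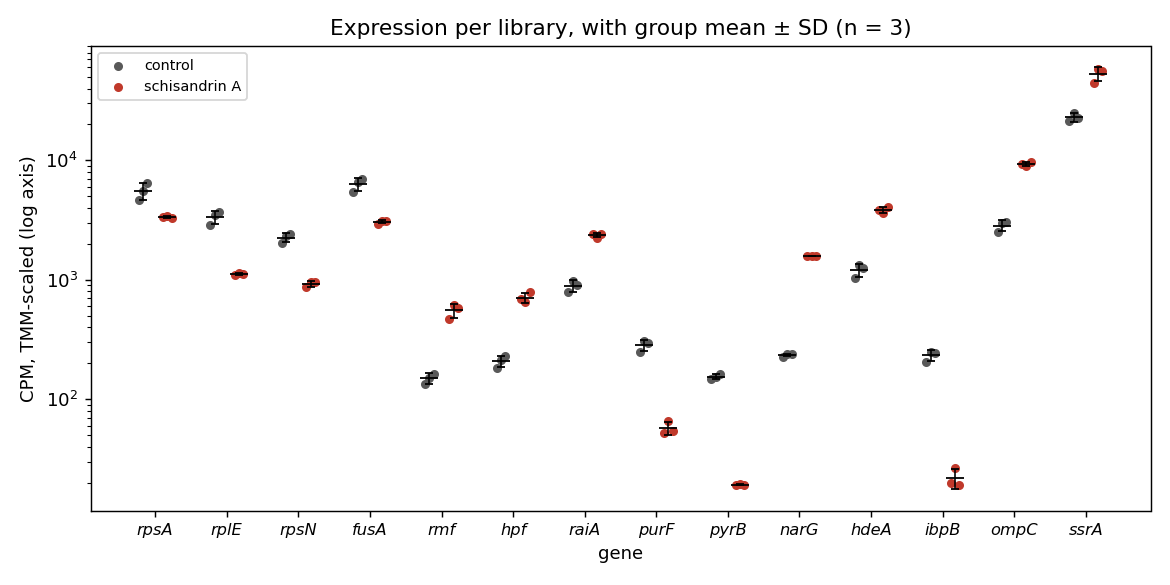
CPM per library on a log axis for 14 named genes, scaled by TMM, in control (grey) and schisandrin A (red) libraries; black marks are the group mean ± SD (n = 3). Control and treated libraries do not overlap for any gene shown, with rpsA going from 5594 to 3368 CPM and rmf from 150 to 554 CPM.

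Other parts of the translation machinery were lower too. Among 17 translation factors, 10 fell and 2 rose, def by 0.69 and map by 0.28, the latter being -0.06 with library size alone. The elongation factor G gene fusA fell from 6314 ± 794 to 3067 ± 89 CPM, and tsf (elongation factor Ts) and prfB (release factor 2) fell by 1.08 and 1.09 on the log2 scale. The call of tufB, at under 10 CPM and sharing near-identical sequence with tufA, is uncertain; without control replicate 2 its adjusted p was 0.0642 (edgeR), within a range of 0.00276 to 0.108 over all alternatives. Among 22 aminoacyl-tRNA synthetases 16 fell, led by metG (-1.31 ± 0.12) and lysS (-1.22 ± 0.11), and serS alone rose, by 0.40 (0.07 with library size alone). Among 39 genes of ribosome assembly and rRNA modification 25 fell and 4 rose (rimJ, rsmD, rsmH and yihI); with library size alone 32 fell and yihI alone rose. On the TMM scale rhlE, an RNA helicase gene, was at -1.38 ± 0.12 and the 30S maturation factor gene rimM at -1.23 ± 0.11. For these lists camera gave adjusted p-values of 0.00746, 0.000192 and 1.95e-05 (adjusted p = 0.745, 0.745 and 0.698 with an estimated correlation), and the counts adjusted over the list alone were identical.

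Genes of the ribosome hibernation list, some of whose products hold ribosomes inactive, were more often higher than lower. Of 10 genes 7 rose and 2 fell, rsfS (-0.61) and ettA (-0.30), with the same counts adjusted over the list alone, and with library size alone 5 rose and 3 fell. The 100S dimer factor gene rmf rose 3.7-fold, from 150 ± 14.9 to 554 ± 73.3 CPM. The hibernation promoting factor gene hpf rose 3.4-fold and raiA 2.66-fold, and elaB, for an inner-membrane protein, rose 2.11-fold. The RpoS list also holds elaB, sra and ygaM. The list had an adjusted p of 0.000381 by camera (adjusted p = 0.591 with an estimated correlation). Its genes were short (median 312 nt). The list median of 0.63 lay inside the range of lists matched on coding length and expression (95% between -0.42 and 0.93). The list median therefore did not stand apart from other short genes of like abundance. That comparison does not cover single genes such as rmf, hpf and raiA.

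Nucleotide synthesis fell in both branches. Of 17 purine genes 15 fell, with a median log2 fold change of -1.32, and 1 rose, purA for adenylosuccinate synthetase, by 1.30. Of 12 pyrimidine genes 10 fell, with a median of -1.43, and none rose. The counts adjusted over the list alone were identical. Camera's adjusted p was 8.38e-13 for purine and 7.64e-10 for pyrimidine synthesis (adjusted p = 0.460 and 0.373 with an estimated correlation).

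In the list of nitrogen assimilation and threonine, lysine and glutamate synthesis, 14 of 28 genes fell and 5 rose (15 and 6 when adjusted over the list alone). The 5 that rose were asd and the lysine-branch genes dapA, dapB, dapD and dapF, and with library size alone only dapD kept its call. Beside glnA, the asparagine synthetase gene asnB fell from 1288 ± 157 to 306 ± 24.4 CPM, and glnP and glnL, for glutamine uptake and nitrogen regulation, were at -1.59 ± 0.13 and -1.48 ± 0.17. The list's adjusted p by camera was 0.000165 (adjusted p = 0.648 with an estimated correlation). In the arginine synthesis list 4 of 15 genes fell and 1 rose, with the same counts adjusted over the list alone, but 10 fell and 1 rose with library size alone. On the TMM scale the falls were in carA and carB, which the pyrimidine list also holds, and in the uptake genes artM (-0.67) and artQ (-0.42). The repressor gene argR rose by 1.22. That list had an adjusted p of 0.0266 by camera (adjusted p = 0.460 with an estimated correlation). It was 0.0519 without schisandrin A replicate 2, 0.0920 with library size alone and 0.0516 under a stricter count filter, in a range of 0.00212 to 0.460 over all alternatives.

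Catabolic genes of amino acids rose in 19 of 34 cases and fell in 3 (glyA, puuP and sdaA), with the same counts adjusted over the list alone, but 17 rose and 13 fell with library size alone. The anaerobic threonine pathway genes tdcC and tdcB rose 5.27-fold and 4.34-fold, and tdcA rose by 1.94 ± 0.16 (log2), and glyA, for serine hydroxymethyltransferase, fell from 947 ± 129 to 256 ± 15.2 CPM. The adjusted p was 0.000843 by camera (adjusted p = 0.685 with an estimated correlation). It was 0.0829 with library size alone and ranged from 0.000293 to 0.685 over all alternatives.

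Chaperone and heat-shock genes fell in 16 of 20 cases and rose in 3, clpA, clpP and clpX, which encode subunits of Clp proteases; clpX rose by 0.29 but was at -0.05 with library size alone. Beside ibpB, the protease ATPase gene hslU fell from 1873 ± 231 to 640 ± 35.8 CPM, htpG from 1306 ± 156 to 457 ± 13.1 CPM, and ibpA from 323 ± 31.4 to 114 ± 7 CPM. Protein export genes fell in 8 of 16 cases and rose in 1, secB by 0.30 (-0.04 with library size alone). With library size alone 12 fell and 0 rose. On the TMM scale the translocation ATPase gene secA was 3.16-fold and the membrane insertase gene yidC 2.44-fold lower. The counts of these lists adjusted over the list alone were identical. Camera's adjusted p was 5.61e-09 for chaperones and 0.0379 for protein export (adjusted p = 0.591 and 0.745 with an estimated correlation). Without control replicate 3 the protein export list had an adjusted p of 0.0781, in a range of 0.00254 to 0.745 over all alternatives.

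In 4 stress lists rises outnumbered falls. In the acid resistance list 13 of 17 genes rose and 3 fell, the latter being adiA, adiC and adiY of the arginine-dependent system. The periplasmic chaperone gene hdeA rose from 1207 ± 147 to 3865 ± 213 CPM and hdeD rose 4.31-fold; gadA rose 4.12-fold, but it shares near-identical sequence with gadB, which rose by 0.79. In the general stress list of the sigma factor RpoS, 21 of 27 genes rose and 3 fell (bsmA, ecnB and katE; 14 and 6 with library size alone), with osmY going from 1217 ± 116 to 4017 ± 207 CPM and wrbA from 743 ± 125 to 2325 ± 156 CPM. In the SoxRS and OxyR oxidative stress list 18 of 28 genes rose and 4 fell (gor, katE, nfo and oxyR). There the superoxide dismutase gene sodB rose 2.91-fold, soxS 2.68-fold, sufA by 1.38 ± 0.12 (log2), and the DNA-protecting ferritin gene dps, which the RpoS list also holds, 2.49-fold. In the SOS list 10 of 21 genes rose and uvrA alone fell (11 and 1 adjusted over the list alone), but 8 rose and 6 fell with library size alone, where the list median of 0.36 became 0.02. On the TMM scale the division inhibitor gene sulA went from 99.4 ± 9.51 to 351 ± 12 CPM, and recN rose 3.35-fold and lexA 2.71-fold. The other 3 lists kept their counts when adjusted over the list alone. By camera the adjusted p was 1.21e-10 for acid resistance, 3.90e-07 for RpoS, 1.85e-06 for oxidative stress and 0.00161 for SOS (adjusted p = 0.373, 0.591, 0.591 and 0.618 with an estimated correlation).

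**Figure D2:**
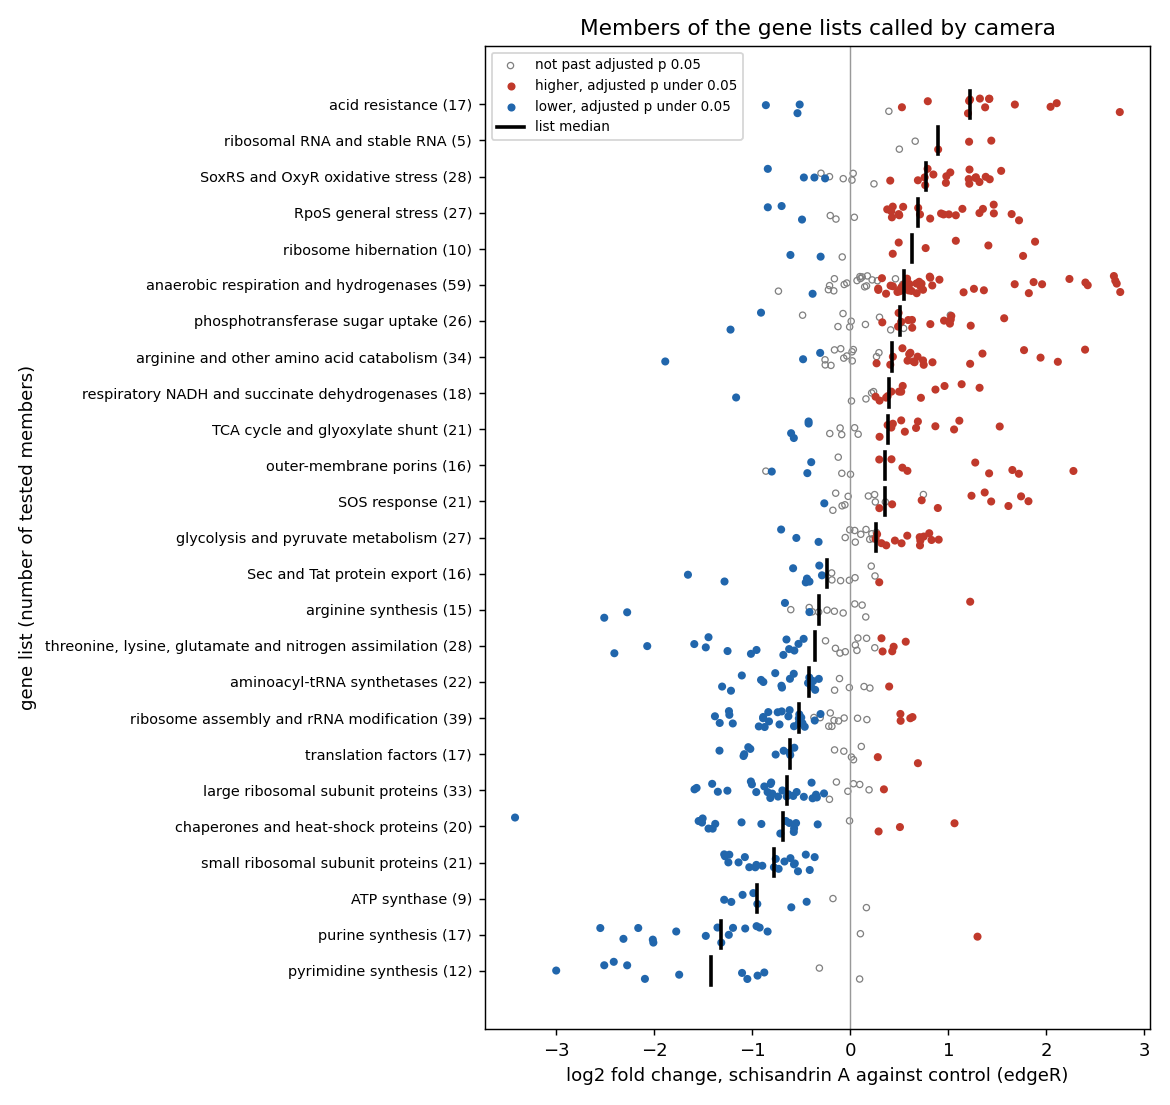
Log2 fold change (schisandrin A against control) of every tested member of the 25 gene lists that camera called with its preset correlation, ordered by list median (black bar). Red and blue points are genes higher or lower at an adjusted p under 0.05, and open points did not pass; pyrimidine synthesis (median -1.43) lies at the bottom and acid resistance (median 1.22) at the top.

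Energy metabolism changed in both directions. In the anaerobic respiration and hydrogenase list 40 of 59 genes rose and narZ alone fell, led by narG, narH, narJ and narI, at an adjusted p of 1.32e-11 by camera (adjusted p = 0.373 with an estimated correlation). In contrast, 7 of the 9 ATP synthase genes fell and none rose, with atpE at -1.29 ± 0.12 and atpB at -1.10 ± 0.11 and a list p of 0.000381 after adjustment by camera (adjusted p = 0.60 with an estimated correlation). NADH and succinate dehydrogenase genes rose in 13 of 18 cases (14 adjusted over the list alone). Here nuoN rose 2.5-fold, and only ndh, for the NADH dehydrogenase that does not pump protons, fell, 2.24-fold. In the TCA cycle list 12 of 21 genes rose and 4 fell (aceA, aceB, aceK and mqo), with sucD 2.88-fold and the citrate synthase gene gltA 2.16-fold higher. In the glycolysis and pyruvate list 14 of 27 rose and ackA, acs and pta fell (15 and 3 adjusted over the list alone), with pfkB at 0.90 ± 0.11 and ppsA at 0.83 ± 0.11, although the list median of 0.27 became -0.07 with library size alone. With library size alone the anaerobic list had 28 rises and 3 falls, the dehydrogenase list 7 and 4, the TCA list 9 and 8 and the glycolysis list 9 and 9. Counts of the anaerobic, ATP synthase and TCA lists were identical when adjusted over the list alone. The dehydrogenase and TCA lists share sdhA, sdhB, sdhC and sdhD. For the dehydrogenase, TCA and glycolysis lists the adjusted p by camera was 0.00637, 0.0379 and 0.0354 (adjusted p = 0.745, 0.868 and 0.885 with an estimated correlation). With library size alone these were 0.0750, 0.232 and 0.622, and the glycolysis value was 0.0883 without control replicate 1. Over all alternatives they ranged from 0.00116 to 0.745, 0.00889 to 0.868 and 0.00643 to 0.885.

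Sugar uptake through the phosphotransferase system rose in 14 of 26 genes and fell in chbA and chbB (14 and 3 adjusted over the list alone; 10 and 5 with library size alone). The mannose transporter genes manZ and manY rose 2.97-fold and 2.34-fold, fruB was at 1.03 ± 0.15, and chbB of the chitobiose system was at -1.22 ± 0.28. In the outer-membrane porin list 9 of 16 genes rose and fadL, ompF and ompG fell (9 and 4 adjusted over the list alone), but 6 rose and 6 fell with library size alone, where the list median of 0.36 became 0.03. The major porin gene ompC rose from 2844 ± 298 to 9374 ± 328 CPM, ompW rose 3.15-fold and slp, which the acid list also holds, 2.67-fold. The porin list also holds genes that do not encode porins, among them slp, lpp, ompR and envZ. These lists had adjusted p-values of 0.00274 and 0.0133 by camera (adjusted p = 0.591 for each with an estimated correlation).

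Of the 5 stable and ribosomal RNA genes with enough counts, 3 rose and rrlA and ffs did not pass the test, with the same counts adjusted over the list alone. Transfer-messenger RNA, ssrA, went from 22956 ± 2003 to 53197 ± 7310 CPM, the RNase P RNA gene rnpB from 4290 ± 46.9 to 11634 ± 2001 CPM, and 6S RNA, ssrS, from 391 ± 39.6 to 728 ± 32 CPM. All non-coding RNA genes together took 5.26% ± 0.183 of counts in controls and 10.5% ± 0.809 with schisandrin A (SD, n = 3). Most of that was ssrA, at 2.58% ± 0.192 and 4.72% ± 0.608, and the regulatory RNA csrB, at 2.03% ± 0.275 and 4.52% ± 0.104. Reads counted in ribosomal RNA genes were 0.0028% ± 0.000778 and 0.00249% ± 0.000483 of counts. The rRNA removal and the counting settings are not given, so these shares may not be the rRNA content of the libraries. Camera's adjusted p for the list was 0.00317 (adjusted p = 0.373 with an estimated correlation). With no count filter it was 0.219, in a range of 0.00142 to 0.373 over all alternatives.

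The other 26 of the 51 lists tested did not pass with camera. Among them the RNA polymerase list had an adjusted p of 0.0307 without control replicate 1 and 0.00131 with library size alone (0.00131 to 0.868 over all alternatives). The osmoprotection list had 0.0428 without schisandrin A replicate 2 (0.0116 to 0.745 over all alternatives). Cold-shock genes went both ways, with cspD rising by 2.12 ± 0.13 and cspG falling by 1.55 (log2). Among 12 terminal oxidase genes 5 rose and 7 fell, with appB at 1.02 ± 0.11 and cyoA at -0.82 ± 0.11. Of 40 genes of peptidoglycan synthesis and cell division 13 rose and 10 fell (14 and 11 adjusted over the list alone), and of 32 genes of lipid A and LPS core synthesis 10 rose and 7 fell with the same counts adjusted over the list alone. The balance reversed with library size alone, to 8 rises and 25 falls for peptidoglycan and 7 and 17 for lipid A, and with upper-quartile factors, to 12 and 16 and to 10 and 13. In the lipid A list, waaA was at -1.27 ± 0.15 and lpxC, for the committed step of lipid A synthesis, went from 1676 ± 158 to 3364 ± 112 CPM. Among 34 flagellar genes 29 did not pass the test, 2 rose and 3 fell (2 and 2 adjusted over the list alone; 0 and 9 with library size alone), with the master regulator genes flhC and flhD at -0.75 ± 0.12 and -0.74 ± 0.14. Of the flagellar rises, fliA lost its call without schisandrin A replicates 1 or 3 (adjusted p = 0.0543 and 0.0629, edgeR; 0.00862 to 0.151 over all alternatives). Of 8 type 1 fimbrial genes fimD and fimI fell, with the same count adjusted over the list alone, but both calls were lost without control replicate 1 (adjusted p = 0.0608 and 0.120, edgeR). The call of fimI was also lost without schisandrin A replicate 1 (adjusted p = 0.123, edgeR), and over all alternatives fimD ranged from 0.000440 to 0.859 and fimI from 0.00245 to 0.440. Of 15 curli and cellulose genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; 0 and 4 with library size alone). Of 30 efflux and Mar-Sox-Rob genes 8 rose and 6 fell, with the same counts adjusted over the list alone, but 1 rose and 14 fell with library size alone and 6 and 8 with upper-quartile factors. The flagellar list had a median of 0.21 but was ranked down by camera, and the curli list had a median of 0.29 and a mean of -0.05, and neither passed. In the peptidoglycan, LPS and efflux lists the median and the mean likewise differed in sign, close to 0.

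Virulence genes could be examined only where K-12 carries the gene. Of 57 extraintestinal virulence symbols 4 were among the gene models and 3 were tested, too few for a list test. They were aslA (0.53 ± 0.19), focA (0.37 ± 0.12) and malX (-0.20). In these gene models focA is the formate channel, not the fimbrial gene of that symbol, and its value was 0.04 with library size alone. The deposited annotation places malX in a sugar phosphotransferase family, so its match to a virulence gene by symbol alone is uncertain too. The aslA call was lost without control replicate 2 and without schisandrin A replicates 2 or 3 (adjusted p = 0.0554, 0.174 and 0.0650, edgeR), in a range of 0.0123 to 0.921 over all alternatives.

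All list calls rest on camera's preset correlation of 0.01. With the correlation estimated from these 6 libraries no list passed and 5 had an unadjusted p under 0.05, whereas fry, which asks only whether a list's own genes moved on balance one way, called 24 of the 25 at an adjusted p under 0.05. In a comparison chosen after the values were seen, 10000 lists matched on length and expression were drawn for each called list, and 16 of the 25 medians lay outside the central 95% of theirs. The 9 inside were ribosome hibernation, porins, SOS, NADH and succinate dehydrogenases, TCA cycle, glycolysis, arginine synthesis, protein export and stable RNA. The matched genes were drawn independently, so these ranges do not allow for correlation between members of a list. The estimated correlation had a median of 0.27 over the 51 lists. The medians outside their ranges therefore add no support beyond the preset correlation. Growth state was not recorded in the labels, so differences in culture density between the groups cannot be separated from the treatment.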

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

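The count of 1851 changed genes stayed within 1.5 times under every alternative except the test against a minimum fold change of 1.5, which called 553 genes (336 higher, 217 lower). Leaving out single libraries gave 1591 to 1830 changed genes, 809 to 956 higher, 718 to 885 lower and 408 to 454 changed at least 2-fold. DESeq2 called 1656, with 239 adjusted p-values left undefined by its filter, limma-voom 1835 and limma on log2(FPKM + 1) 1650. Of the calls shared with the main test, none changed sign in any alternative. With library size alone, 531 genes were higher and 1650 lower, and upper-quartile factors gave 836 and 1047; these scalings moved the median gene by -0.34 and -0.10 (log2). The number of lists called by camera was 25, between 24 and 25 without single libraries, 21 with library size alone, 0 with an estimated correlation (5 at an unadjusted p under 0.05), and 32 and 49 by fry in its directional and either-direction tests. Among the list-test alternatives, the tests of the large and small ribosomal subunit proteins changed their call only with an estimated correlation. Camera's adjusted p was then 0.591 for each, the highest in ranges from 2.73e-18 and 1.16e-17. The estimate rests on 4 residual degrees of freedom. Of 197 genes chosen by the naming rule, 137 lost no call in any alternative and none reversed. The alternatives there include the test against a minimum fold change of 1.5, a stricter question. A call lost only in that test does not show dependence on processing. Replicate numbers are shared between the groups, but same-numbered libraries did not deviate together: their correlations ran from -0.0978 to 0.111, and 2 of 6 libraries correlated best with their own number. A fit with the replicate number as a block gave 1836 genes (965 higher, 871 lower) and 25 lists. A count of 3 corresponds to 1.07 to 1.79 CPM, and genes below the count filter were not tested.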

Other observations

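The tests of ribosomal protein genes, stable RNAs, Pfam families and chromosome position were chosen after the main result was seen. The composition comparison and the matched test of stable RNAs were chosen after the values they rest on were known. Outside the lists, the deposited annotation allowed 200 Pfam families with at least 5 tested members to be tested with camera, and 5 passed, 2 higher and 3 lower. All 6 genes of the universal stress protein family rose, with a median log2 fold change of 1.56 (adjusted p = 2.05e-09, and adjusted p = 0.979 with an estimated correlation). Among them uspD went from 232 ± 15.2 to 985 ± 29.8 CPM and uspF from 441 ± 50.5 to 1823 ± 88.1 CPM (SD, n = 3); uspA is also in the RpoS list. Of 8 members of the permease family that carries nucleobases, 7 fell and none rose, with a median of -0.90 (adjusted p = 0.0145, and adjusted p = 0.979 with an estimated correlation), among them adeP and ghxP, at -1.29 ± 0.12 and -1.20 ± 0.14, and uraA, also in the pyrimidine list, at -0.95 ± 0.16. These uptake genes fell alongside the purine and pyrimidine synthesis genes, with no member of the family passing in the other direction. In 14 proteins with a helicase C-terminal domain, 9 genes fell and none rose, with a median of -0.58 (adjusted p = 0.0041, and adjusted p = 0.979 with an estimated correlation). The overlapping DEAD/DEAH box family had 8 of 13 genes lower (adjusted p = 0.0271, and adjusted p = 0.979 with an estimated correlation); rhlE, deaD, srmB and dbpA in these families are also in the ribosome assembly list. In the iron-containing alcohol dehydrogenase family 5 of 7 genes rose (adjusted p = 0.0041, and adjusted p = 0.979 with an estimated correlation), among them yqhD with a log2 fold change of 2.31 ± 0.12.

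Some genes outside the lists also rose; they were picked after their values were seen. The methylcitrate pathway genes prpC and prpD, for propionate use, rose from 180 ± 26.2 to 864 ± 39.7 CPM and from 241 ± 16.4 to 993 ± 27.3 CPM. The biofilm regulator gene bssR, among the most abundant mRNAs, rose from 5740 ± 627 to 24150 ± 1090 CPM. The ethanolamine microcompartment gene eutM rose from 32.7 ± 3.88 to 128 ± 0.81 CPM.

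The ribosomal protein genes fell by a median of 0.73 (log2), and technical and positional explanations were considered. A shift in composition acts as a factor per library and moves all genes alike, so it cannot change the gap between ribosomal protein genes and other genes. With library size alone, their median minus that of the 3776 other genes was -0.71, with an upper 95% bootstrap bound of -0.55. That gap restates the fall relative to other genes and is not a separate test. A bias against short genes is argued against by 10000 lists matched on coding length and expression, whose medians had a lower 2.5% bound of 0.41, and a location near the replication origin by lists matched on distance from it, with a lower bound of -0.30. What stays open is whether the fall is a response to schisandrin A itself or to a slower or later growth state of the treated cultures, which the design does not separate.

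Several abundant non-coding RNAs rose with schisandrin A: of 6 picked RNAs (csrB, csrC, ffs, rnpB, ssrA and ssrS) 5 passed the test, with a median log2 fold change of 1.33. Of 38 genes of the ncRNA class 7 rose and none fell, csrB, csrC, rnpB and ssrS among the 7. Of 25 tRNA genes tested 1 rose and 5 fell, with a median of -0.02. All tRNA genes together held only 648 to 1347 counts per library, so they cannot show whether the rise extended to tRNA. The CsrA-binding RNAs csrB and csrC rose from 18239 ± 3926 to 50901 ± 1996 CPM and from 216 ± 40.7 to 670 ± 29.4 CPM. The low ffs, at 4.11 CPM in controls and 5.87 CPM with schisandrin A, did not pass. A larger share of short fragments in treated libraries stays open. The median of all 560 protein-coding genes of at most 400 nt was 0.09, with an upper 95% bootstrap bound of 0.16, but that set holds many genes of low expression. Lists of coding genes matched to the 6 RNAs on length and expression had a median of 0.82, with 95% of lists between 0.14 and 1.42, a range that holds the 6 RNAs' own median. For 2 of the 6 no short coding gene was as abundant, so the match is incomplete there. Lists matched to the ribosomal protein genes in the same way had a median of 0.65 (0.41 to 0.88), against 0.26 when matched on expression alone. The rise did not come from the TMM factors, as the median was 0.98 with library size alone.

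A lower replication rate would lower genes near the origin relative to those near the terminus. Across 3830 genes, which are not independent replicates, Spearman's rho of the log2 fold change with distance from the origin was 0.017 (Pearson's r 0.023; circular-shift p = 0.14, 10000 shifts), and 0.0038 without the ribosomal protein genes. The median of the 958 genes farthest from the origin exceeded that of the 958 nearest by 0.0037, with a 95% bootstrap interval of -0.057 to 0.093. A dosage change of the size of the ribosomal fall lies outside that interval. The positions are those of MG1655, not of ATCC25922.

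Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 1851 genes and the highest of the others gave 0, so 1 of the 10, the real split itself, reached that count. Each other split mixed control and treated libraries, so the difference between the groups entered its within-group spread. Its count of 0 therefore adds no support to the count of the real split.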
